A study of Danio rerio with 9 samples.

How the data were processed

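RNA sequencing libraries were prepared by the submitters from total RNA of zebrafish embryos after polyA selection, per the labels' protocols. The 9 libraries were grouped by their titles into 3 groups of 3: control MO, sf3b1 MO, and sf3b1 MO + As2S2. MO stands for morpholino, an antisense oligonucleotide, and As2S2 is an arsenic sulfide. Neither the age of the embryos nor the dose is in the labels used here. Per the submitters' processing notes, fastp 0.22.0 and DESeq2 were used with the GRCz11 assembly, and the aligner, assembler and counting program are not given in the sources used here.

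All values came from 1 deposited table. Whole-number counts per gene are given by the authors for the 6 control MO and sf3b1 MO libraries, under headers that read wt and ko in the deposited table. These were taken as control MO and sf3b1 MO: across genes, the deviation of each library's counts from its group mean followed that of the FPKM of the library with the same name and number (Spearman correlation 0.952 to 0.958) and of no other library of its group (at most -0.394). FPKM values (fragments per kilobase of transcript, scaled to the size of the library) are deposited for all 9 libraries, with the unit read from the table's mean column, which per the file headers holds a mean of FPKM. That column is on the log2 scale: the authors' deposited mean equals the mean of log2(FPKM + 1) over the 6 control MO and sf3b1 MO libraries in 20712 of 20723 genes, within 0.001. The authors' deposited log2 fold changes and p-values compare the same 6 libraries. Of these, only the log2 fold changes were used here, for single genes.

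The table has 21137 lines, of which 14 are blank and 14 hold fragments of text. Of the 21109 genes or transcripts, 18042 have an Ensembl identifier and 3067 are assembled transcripts with none. Control MO and sf3b1 MO values are given for 20723, As2S2 values for 20146, and both for 19760. The As2S2 columns therefore look joined from a table with another gene list, and whether all 9 libraries were normalized together is not given in the sources used here. Gene names were taken from the table, or for 1244 genes named there by identifier alone from a table of names; 17481 identifiers matched it. The table gives no coordinates.

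The design written before the data were examined assumed counts for all libraries. As counts are given for 6, sf3b1 MO against control MO was tested on counts, with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, robust fit, default expression filter, which removed no gene). Both comparisons of the As2S2 libraries were tested on FPKM with limma 3.58.1 on log2(FPKM + 1), with 1 as pseudocount, over the 18013 genes of at least 1 FPKM in 3 or more libraries. All 9 libraries entered 1 fit with a mean per group and a trend of the variance. Fold changes on this scale understate the change of genes at low FPKM. Adjusted p-values are Benjamini-Hochberg over all genes tested, with 0.05 as threshold. In the As2S2 comparisons the median log2 fold change over all genes was -0.20 against sf3b1 MO and -0.25 against control MO. Log2 fold changes of single genes are therefore given relative to this median gene, while calls refer to the unshifted values, and splits after centring each library on its median are given where they differ most.

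Total counts per library were 28702980, 25177824 and 26384381 in control MO and 21942696, 22861664 and 26197696 in the libraries labelled sf3b1 MO. The depth of the As2S2 libraries is unknown. The common biological coefficient of variation in edgeR, a single value over all genes, was 0.20. Well-counted genes such as sf3b1 varied far less between libraries of a group. As no label says that replicates came from separate clutches, 0.20 need not measure variation between clutches. Counts were simulated with the same means and depths and with 0.20 as coefficient of variation for every gene. There, edgeR found 61% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, with 7 other calls among 20723 genes. For genes that vary less than this, the share found would be understated. FPKM were simulated with each gene's own spread, so the shares from counts and FPKM cannot be compared. In simulated FPKM, limma found 95% of 100 genes changed 2-fold for As2S2 against sf3b1 MO, with 6 other calls among 18013 genes. For As2S2 against control MO it found 97%, with 11 other calls.

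24 gene lists of tissues, cell types and pathways, 764 symbols in all, were written before the data were examined; 679 symbols were found in the table. Each list with at least 5 tested genes was tested with camera of limma, two-sided, with a preset correlation of 0.01 between genes and again with a correlation estimated from the data. The genes named were fixed by a rule: sf3b1 and smad7; the 6 largest rises and 6 largest falls among called genes with a mean of at least 4 CPM or FPKM over both groups compared and no overlap of the libraries; up to 3 members per list with the smallest adjusted p; and the 8 genes with the largest changes in opposite directions in the first 2 comparisons. Other names were chosen after their values were seen, and are said to be so. Over the genes this rule took, standard errors of the log2 fold changes were 0.03 to 0.75 for sf3b1 MO against control MO, 0.02 to 0.34 for As2S2 against sf3b1 MO and 0.02 to 0.34 for As2S2 against control MO.

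The agreement of counts, FPKM and the mean column was checked gene by gene. FPKM per count was compared between groups, with the FPKM as they stand and with those of both groups exchanged. The mean column was compared with the mean of each of the 84 sets of 6 FPKM columns. The search was tested on exchanges planted in values rebuilt from counts with little noise. Only well-counted genes with a clear difference between the groups were used. It found 20 of 20 exchanged genes and 20 of 20 genes with moved values, with 0 wrong calls. Exchanges in genes with low counts or small group differences could be missed, so the genes found need not be all. FPKM of the control MO and sf3b1 MO libraries were also rebuilt from counts and the mean column as an alternative. FPKM with As2S2 were compared, library by library, with the rebuilt sf3b1 MO values. Other alternatives were DESeq2 1.42.0, limma-voom, other scalings, filters, pseudocounts of 0.1 and 10, a 2-fold threshold, the replicate number as a block, and leaving out each library. Replicate numbers were not used to pair libraries, since nothing in the labels says that they mark a shared clutch or day. R 4.3.3 and Python 3.11.15 were used, with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.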

Results

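The data are RNA sequencing libraries of zebrafish embryos, labelled as trunk tissue, in 3 groups of 3 libraries. Embryos received a control morpholino, a morpholino against sf3b1, which encodes a core protein of the U2 part of the spliceosome, or the sf3b1 morpholino together with As2S2. The stated purpose of the series is the effect of As2S2 on red blood cell maturation through smad7, an inhibitor of TGF-beta signalling. Total counts were 21942696 to 28702980 in the 6 libraries without As2S2 and are not known for the others. Across genes, libraries of 1 group correlated at 0.982 or more on the log2 FPKM scale and libraries of different groups at 0.947 or less. Eye transcripts were abundant in these libraries labelled as trunk: in control MO, the rod opsin rho stood at 929 ± 49.3 FPKM and the lens crystallin cryba1b, chosen after its values were seen, at 849 ± 9.06 FPKM (SD, n = 3). No label says that replicates came from separate clutches, so p-values measure only the spread between these libraries.

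The targeted gene gave opposite answers in the 2 kinds of value. By counts, sf3b1 (ENSDARG00000056138) was higher in the libraries labelled sf3b1 MO, at 877 ± 20.3 against 541 ± 5.92 CPM (counts scaled to the effective library size) in control MO (SD, n = 3; log2 fold change 0.70, SE 0.03, edgeR adjusted p = 2e-10). By FPKM it was lower, at 108 ± 1.75 against 171 ± 4.68, and stood at 169 ± 2.27 with As2S2. In the same way smad7 (ENSDARG00000016858) was higher by counts, at 53.01 ± 3.82 against 39.1 ± 0.844 CPM (log2 fold change 0.44, SE 0.07, adjusted p = 9.8e-05), and lower by FPKM, at 10.2 ± 0.331 against 13.8 ± 1.25, with 17.3 ± 0.984 after As2S2. The log2 fold changes in the authors' deposited table, 0.71 for sf3b1 and 0.45 for smad7, have the sign of the counts. A morpholino can block splicing or translation without lowering the RNA of its target, so the level of sf3b1 does not settle the labels, and the group is called the libraries labelled sf3b1 MO.

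**Figure D1:**
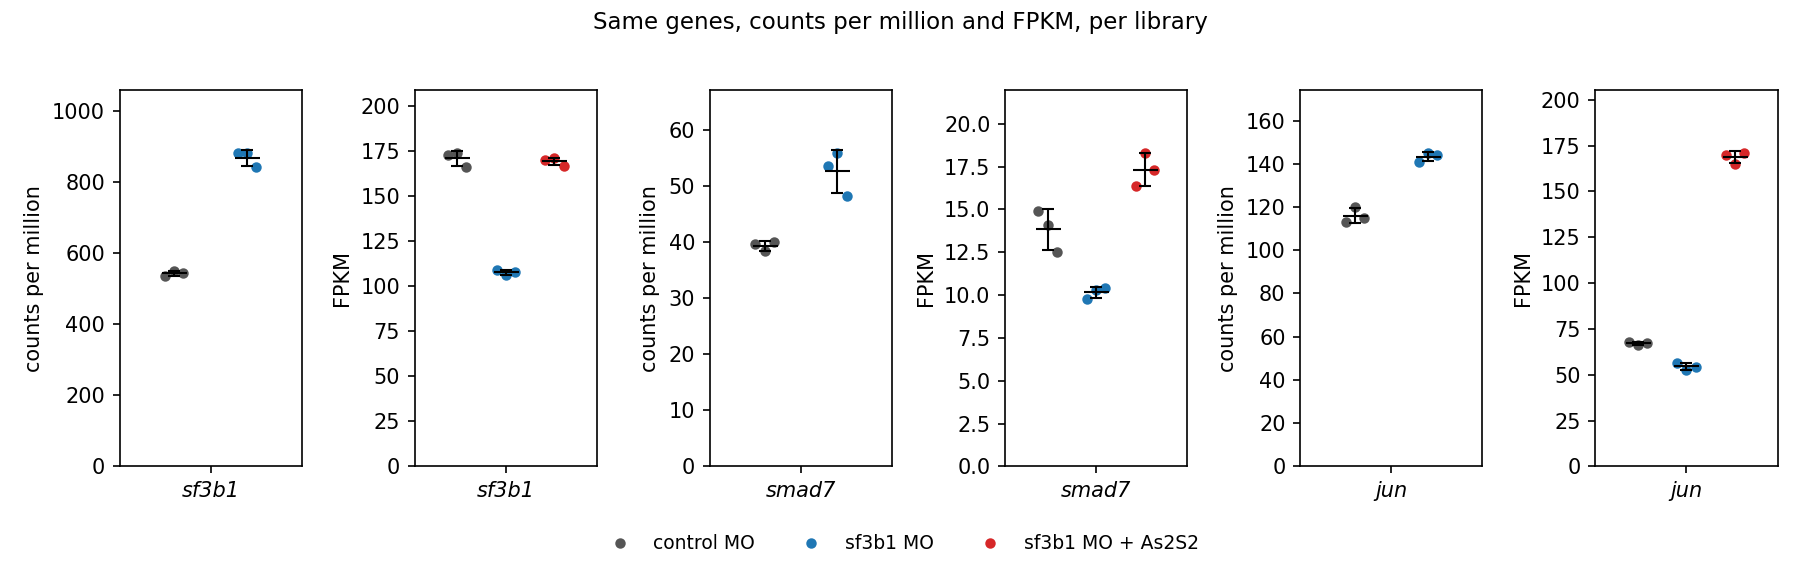
CPM scaled to the plain library total and FPKM of sf3b1, smad7 and jun in each library; dots are libraries, bars the mean and SD of 3 libraries, and all axes start at 0. In each gene the counts are higher and the FPKM lower in the libraries labelled sf3b1 MO than in control MO.

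Across 13430 genes with at least 100 counts in each library, the log2 ratios of the 2 groups from counts and from FPKM correlated at 0.99. They differed by more than 0.5 in 57 genes, and in 10 they had opposite signs with at least 0.2 on either side. In 3 of these genes, sf3b1, smad7 and the transcription factor gene jun, the FPKM of each of the 2 groups followed the counts of the other group. The globin gene hbbe3, with lower counts, did so too. It was found by a separate search of genes with at least 5 counts in each library, which saw only large mismatches. With the groups exchanged, the SD of log2 FPKM per count fell from 0.734 to 0.000 in sf3b1, from 0.484 to 0.027 in smad7, from 0.335 to 0.000 in jun and from 4.614 to 0.074 in hbbe3. In 11 other genes the deposited mean column differed from the mean of the 6 FPKM values by at least 0.089 on the log2 scale: alas2, hbbe2, tal1, hbae3, hbae4, hbae1.2, hbae1.3, hbbe1.2, hbbe1.1, hbbe1.3 and sp1. Of these, 10 are among the 63 measured members of the 4 blood lists (exact hypergeometric p = 3.5e-25), and 8 are among the 9 globin genes of the table. In each of the 11 genes, exactly 1 of the 84 sets of 6 FPKM columns gave the deposited mean within 1e-06. In 9 genes that set was control MO with the 3 As2S2 columns in place of the sf3b1 MO columns. In alas2 and hbbe2 it was control MO with 1 sf3b1 MO and 2 As2S2 columns. In those 9 genes the FPKM with As2S2 also matched, library by library and within 0.05 on the log2 scale, the sf3b1 MO values rebuilt from counts and the mean column. For hbae1.3, for example, the former were 287.26 ± 26.60 and the latter 287.25 ± 26.61 FPKM (SD, n = 3). Of 276 genes whose rebuilt and deposited sf3b1 MO values differ by more than 0.1 on that scale, 11 matched in this order of libraries, sf3b1 and sptan1 being the others, and 2 to 6 in the other orders. The mean column sets the overall level of the rebuilt values, so agreement in level is partly built in. Ratios between libraries come from the counts. Apart from sf3b1 and smad7, these 15 genes were singled out after their values were seen. For sf3b1 and the 11 genes with a differing mean, no effect of As2S2 can be assigned from the table. In smad7, jun and hbbe3 the FPKM with As2S2 lay above those of both other groups, with the FPKM of those groups as deposited or rebuilt from counts. All 15 stay in the counts of genes and lists below; without them 11122 genes in place of 11139 were called for As2S2 against sf3b1 MO and 12242 in place of 12249 against control MO.

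**Figure D2:**
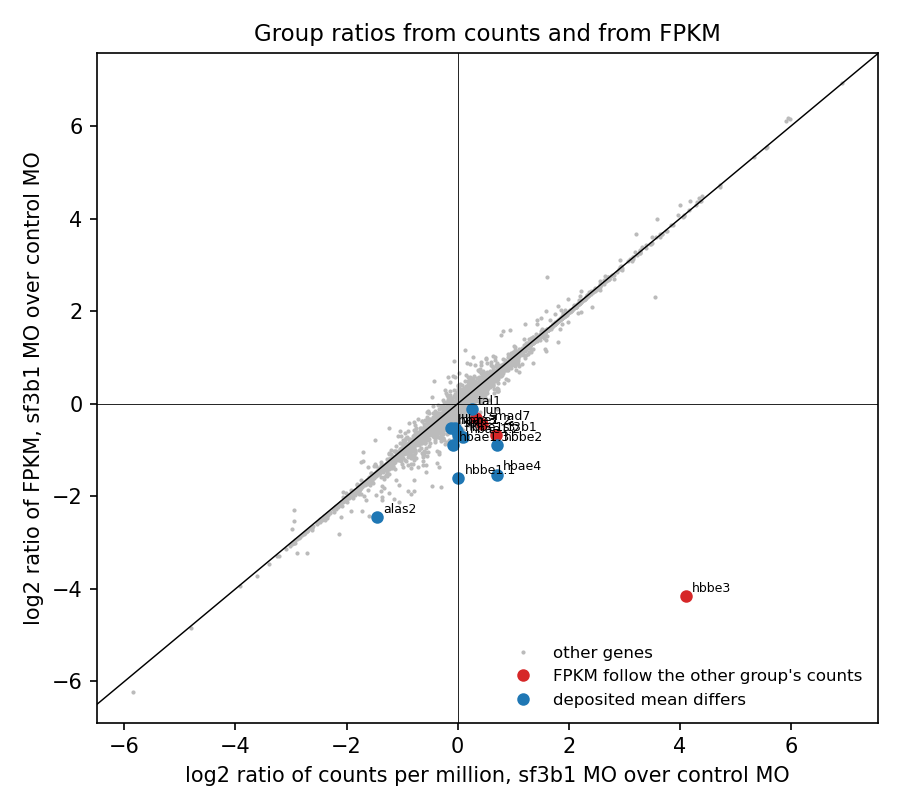
Log2 ratio of the libraries labelled sf3b1 MO over control MO from mean CPM (x) and mean FPKM (y), 1 point per gene for 17998 genes, with the line of equality; red, the 4 genes whose FPKM follow the other group's counts; blue, the 11 genes whose deposited mean differs. The log2 ratio of the globin gene hbbe3 was -4.16 by FPKM and 4.09 by CPM scaled to the plain library total. In 94.2% of 13430 genes with at least 100 counts in each library, both log2 ratios differed by less than 0.1. That share was computed with 1 scaling factor per library, not from the plotted points.

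The first comparison asks what the sf3b1 morpholino changed, and rests on counts. Transcripts of skeletal muscle, connective tissue and epidermis were lower in the libraries labelled sf3b1 MO. The fast myosin gene myhz2 fell from 3086 ± 39.1 to 817 ± 16.3 CPM (SD, n = 3; log2 fold change -1.92, SE 0.03), the actin gene acta1b from 2871 ± 26.9 to 799.9 ± 16.6 (-1.84) and myhz1.3 by 1.93 on the log2 scale. The type I collagen genes col1a1b (-1.74), col1a1a (-1.71) and col1a2 (-1.57) and the keratin genes cyt1l (-2.17), cyt1 (-1.89) and krt91 (-1.38) fell as well. Of 36 muscle genes tested, 34 fell and 0 rose (camera adjusted p = 2.5e-17); of 26 collagen and matrix genes, 24 fell and 1 rose (adjusted p = 1.1e-10); of 29 epidermal genes, 25 fell and 0 rose (adjusted p = 3.6e-11). These 3 lists were called with an estimated correlation too, each at adjusted p = 0.018.

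Of all 20723 genes, 10592 were called by edgeR, 5232 higher and 5360 lower, and 2437 of them changed at least 2-fold, 827 higher and 1610 lower. Among genes with a mean of at least 4 CPM over both groups, the largest falls were in col8a1a (-3.23), a collagen of the notochord, the mucin gene muc5.2 (-3.05), the fin fold gene and2 (62.97 to 7.86 CPM), the posterior Hox gene hoxc12a (-2.98), fut9d (-2.96) and ugp2a (-2.96). The largest rises in these genes were in msrb1b (4.35, SE 0.75), the arginine methyltransferase gene prmt7 (3.82), the kinase gene wnk1a (3.57), l3mbtl2 (3.32), NAV2 (3.23) and npdc1b (3.15). Of these, wnk1a was the most abundant, at 188 ± 10.1 against 15.8 ± 1.98 CPM (n = 3).

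7 further lists were called with the preset correlation alone. Cell cycle genes fell in 27 of 39 cases and rose in 2 (adjusted p = 1.8e-05; adjusted p = 0.055 with an estimated correlation). Among them were pcna (-0.43), mcm6 (-0.73) and mcm3 (-0.65) of DNA replication. Genes of oxidative phosphorylation fell in 26 of 41 cases and rose in 1 (adjusted p = 0.00035; adjusted p = 0.38 with an estimated correlation), with uqcrc1 at -0.65 and atp5fa1 at -0.45. Of 50 spliceosome genes 23 rose and 7 fell (adjusted p = 0.017; adjusted p = 0.23 with an estimated correlation). Splicing factor genes srsf11 (0.66) and srsf6b (0.58) rose beside sf3b1 itself. TGF-beta pathway components fell in 15 of 29 cases and rose in 5 (adjusted p = 0.024; adjusted p = 0.26 with an estimated correlation). The receptor genes acvr2bb and acvr2aa stood at -1.13 and 0.30, and the ligand gene tgfb3 at -0.71. Of 29 TGF-beta target genes 16 fell and 4 rose, or 19 and 5 adjusted over the list alone (adjusted p = 0.028; adjusted p = 0.20 with an estimated correlation). The matrix genes postnb (-1.82), tgfbi (-1.50) and thbs1b (-0.62) were among those that fell. Of 33 genes of neurons and glia 18 rose and 6 fell (adjusted p = 0.041; adjusted p = 0.27 with an estimated correlation), with syt1a at 0.61, stmn1b at 0.50 and the glial gene gfap at -0.48. Of 22 notochord and pigment genes 12 fell and 5 rose (adjusted p = 0.047; adjusted p = 0.26 with an estimated correlation), with gch2 at -1.55 and epyc at -0.85 by counts, where the log2 ratio of its FPKM was -1.95.

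Blood lists were not called by counts. Of 23 erythroid genes 10 fell and 3 rose (adjusted p = 0.058, and 0.038 without sf3b1 MO replicate 1), with rhag, a membrane protein of red cells, at -1.16, tmod4 at -1.54 and tspo at 0.87. Of 20 genes of heme synthesis and iron uptake 5 rose and 5 fell (adjusted p = 0.84), with the ferritin gene fthl27 at 1.02 and alas2, the first enzyme of heme synthesis in red cells and chosen after its values were seen, at -1.46. Of 9 globin genes 2 rose and 1 fell (adjusted p = 0.44). By the deposited FPKM, which are in question, all 9 were called lower, from -0.52 in hbbe1.2 to -2.57 in hbbe3. Whether near-identical globin genes shared reads was not tested, so their separate levels are uncertain. Heat shock genes were not called as a list (10 rose and 7 fell of 25, adjusted p = 0.16), but hsp70l rose from 40.1 ± 0.993 to 263 ± 7.64 CPM (n = 3; 2.71) and its near-copy hsp70.3 by a log2 fold change of 2.94. The counts of members adjusted over the list alone were the same in 21 of the 24 lists; in oxidative phosphorylation 27 fell and 1 rose, and in ribosome biogenesis 6 rose and 7 fell in place of 7 and 7.

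**Figure D3:**
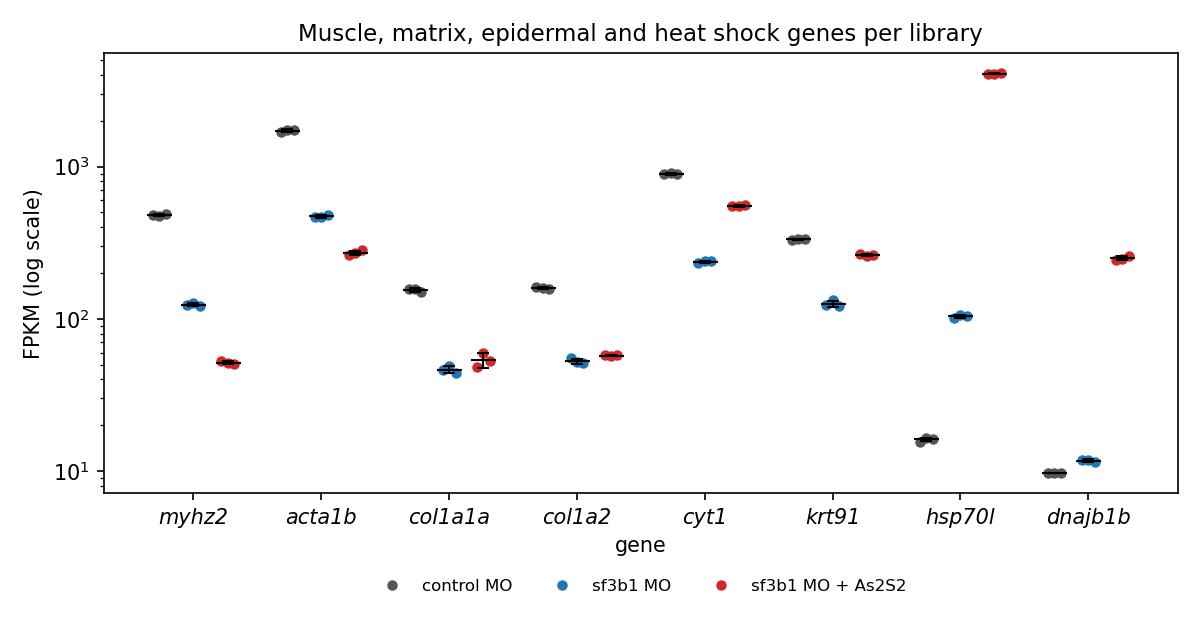
FPKM of muscle (myhz2, acta1b), collagen (col1a1a, col1a2), keratin (cyt1, krt91) and heat shock genes (hsp70l, dnajb1b) per library on a log axis; dots are libraries, bars the mean and SD of 3. Muscle genes are lowest and heat shock genes highest with As2S2, where hsp70l stands at 4084 FPKM.

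The second comparison asks what As2S2 changed in embryos with the sf3b1 morpholino, and rests on FPKM. Heat shock genes rose most: hsp70l went from 104 ± 2.61 to 4084 ± 38.1 FPKM (SD, n = 3; log2 fold change relative to the median gene 5.49, SE 0.03, limma adjusted p = 2.1e-13), and hsp70.1 (5.04), hsp70.2 (4.93), hsp70.3 (4.72), the co-chaperone gene dnajb1b (4.51) and hsp90aa1.2 (3.62) rose with it. Photoreceptor genes fell most: the ultraviolet cone opsin opn1sw1 went from 414 ± 16.8 to 3.09 ± 0.268 FPKM (-6.46) and the rod opsin rho from 809 ± 12.2 to 70.8 ± 2.2 FPKM (-3.29). The green opsin opn1mw1 (-6.34), the red opsin opn1lw2 (-5.47), the cone arrestin arr3a (-5.45) and the cone transducin genes gnb3b (-5.83) and gngt2b (-5.79) fell with them. Cell division genes rose, with nusap1 at 1.51 and tpx2 at 1.42, while ccnd1 went from 25.6 to 64.6 FPKM. Whether near copies among the opsin and hsp70 genes shared reads was not tested, so single members are uncertain.

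Of 18013 genes 11139 were called by limma, 3119 higher and 8020 lower (28.0% higher); with each library centred on its median, 10370 were called, 5435 higher and 4935 lower (52.4% higher). At least 2-fold changes numbered 1713, 444 higher and 1269 lower. Heat shock genes rose in 22 of 25 cases and fell in 1 (camera adjusted p = 2.8e-18), and 23 rose after centring. Cell cycle genes rose in 31 of 39 cases, 32 adjusted over the list alone and 38 after centring, and 0 fell (adjusted p = 7.1e-17). Of 33 eye and lens genes 25 fell, 26 adjusted over the list alone, and 3 rose, with 23 and 4 after centring (adjusted p = 7.3e-06). Muscle genes, already lower in the libraries labelled sf3b1 MO, fell in 31 of 36 cases, 24 after centring, and rose in 1, 2 adjusted over the list alone (adjusted p = 8.8e-06), with myhz1.2 at -1.48, the parvalbumin gene pvalb2 at -1.25 and mylz3 at -1.12. Epidermal genes rose in 14 of 29 cases, 20 after centring, and fell in 5 (adjusted p = 1.5e-05): cyt1 went from 237 ± 3.65 to 553 ± 6.01 FPKM (1.42), and cyt1l (1.48) and krt91 (1.27) rose. Genes of liver, yolk and digestive organs rose in 15 of 23 cases and fell in 4, or 16 and 5 adjusted over the list alone and 16 and 2 after centring (adjusted p = 3.7e-06), with the apolipoprotein genes apoea at 2.86 and apoa2 at 2.50 and the retinol carrier rbp4 at -0.93.

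Stress and signalling lists also moved. Of 34 genes of the unfolded protein response 11 rose and 7 fell, 22 and 2 after centring (adjusted p = 0.00058), with atf3 at 2.33 and the chaperone genes hspa5 at 1.34 and hsp90b1 at 1.03. TGF-beta pathway components rose in 15 of 25 cases and fell in 3, or 15 and 4 adjusted over the list alone and 17 and 2 after centring (adjusted p = 3.4e-05), with the activin receptor gene acvr2ba at 2.65, smad3a at 1.26 and smad4a at 1.16. TGF-beta target genes rose in 11 of 28 cases and fell in 7, or 12 and 7 adjusted over the list alone and 15 and 5 after centring (adjusted p = 0.0096), with cdkn1a at 2.13, junbb at 0.77 and id2a at -0.38. Genes of neurons and glia fell in 26 of 33 cases and rose in 3, 21 and 7 after centring (adjusted p = 0.00019), with snap25b at -0.98 and sypa at -0.88. Notochord and pigment genes rose in 8 of 19 cases and fell in 4, 13 and 2 after centring (adjusted p = 0.0096), and genes of ribosome biogenesis rose in 8 of 36 and fell in 4, or 7 and 2 adjusted over the list alone and 22 and 1 after centring (adjusted p = 0.017), with ddx21 at 0.96. Oxidative phosphorylation fell in 37 of 41 cases, 19 after centring (adjusted p = 0.00013; adjusted p = 0.21 with an estimated correlation), with cycsb at -0.96 and atp5mc1 at -0.84. Of 50 spliceosome genes 16 rose and 9 fell, or 15 and 8 adjusted over the list alone and 34 and 3 after centring (adjusted p = 0.0046; adjusted p = 0.13 with an estimated correlation), with srsf6b at 0.66 and srsf3b at -0.48. 14 of the 16 lists called were called with an estimated correlation too, and 15 of 24 lists had the same counts of members adjusted over the list alone.

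The globin list was called, with 9 of 9 higher (adjusted p = 2.6e-07), but all its members are among the genes in question. In 7 of them the FPKM with As2S2 match the rebuilt sf3b1 MO values, as in hbbe1.1 with 769.36 against 769.29 FPKM, so rebuilt FPKM give no comparison for this list. With rebuilt FPKM, smad7 was higher with As2S2, at 17.32 against 13.66 FPKM, with a log2 fold change of 0.53 relative to the median gene. The limma test (adjusted p = 0.0018) refers to the smaller change without subtracting the median gene. With FPKM as deposited, the log2 fold change relative to the median gene was 0.92. Among erythroid genes outside the question, rhag and tmod4 moved further from control MO: rhag stood at 18.7 ± 0.433 FPKM in control MO, 8.22 ± 0.591 in the libraries labelled sf3b1 MO and 3.36 ± 0.1 with As2S2 (n = 3; -0.88 for As2S2 against sf3b1 MO), and tmod4, also a muscle gene, at 91.8, 28.6 and 13.4 FPKM. The carbonic anhydrase gene cahz stood at 24.6, 28.7 and 13.1 FPKM. Of 22 erythroid genes 6 rose and 12 fell, 7 and 7 after centring (adjusted p = 0.77), and of 18 heme and iron genes 1 rose and 12 fell, or 1 and 13 adjusted over the list alone and 2 and 9 after centring (adjusted p = 0.099). Collagens, oxidative stress and metal response genes, inflammation, endothelium, neutrophils and macrophages, and blood stem cells were not called (adjusted p from 0.067 to 0.74).

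**Figure D4:**
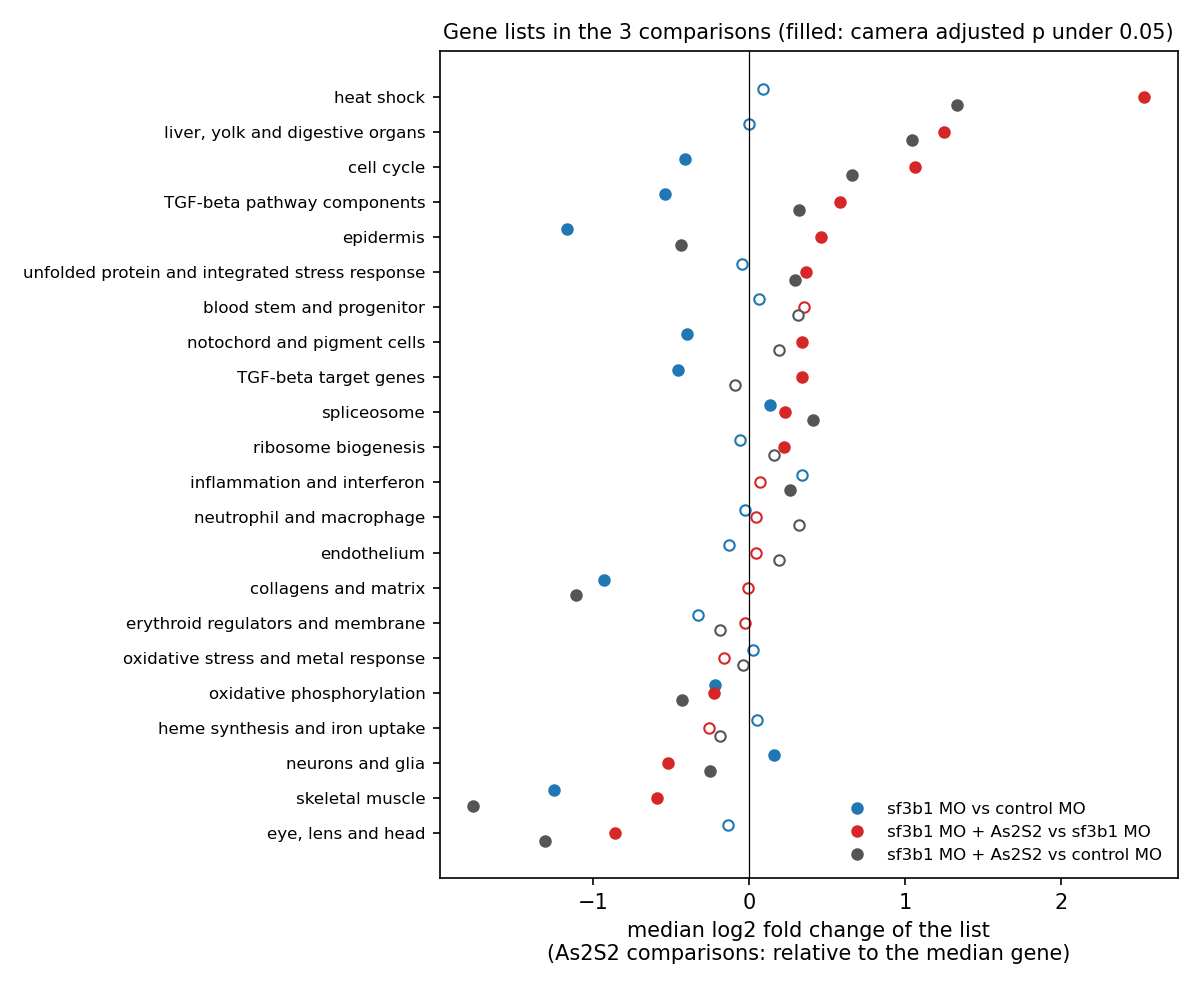
Median log2 fold change of 22 gene lists in the 3 comparisons, relative to the median gene where As2S2 is compared; filled points have a camera adjusted p under 0.05, open points not, the globin list is left out because its FPKM are in question, and 1 more list is not shown. Heat shock lies highest with As2S2, at 2.53 against sf3b1 MO, and skeletal muscle lowest against control MO, at -1.77.

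The third comparison asks how far embryos with As2S2 stood from control MO, on FPKM. They stood further away than sf3b1 MO did in muscle: myhz2 was at 51.5 ± 1.38 against 479 ± 7.09 FPKM (SD, n = 3; log2 fold change relative to the median gene -2.94, SE 0.03, limma adjusted p = 3.8e-12), with myhz1.2 at -2.69 and pvalb2 at -2.56. Collagens stayed low, with col1a1b at 67.0 ± 0.958 against 207 ± 3.2 FPKM (-1.37), col1a2 at -1.21 and the cartilage gene matn1 at -1.91. Keratins lay between both other groups, with cyt1l at -0.68 and cyt1 at -0.44, while the hemidesmosome gene col17a1a was at -2.39. The largest rises were again in hsp70l (8.15), hsp70.1 (7.86), hsp70.2 (7.79), hsp70.3 (7.58), dnajb1b (4.80) and adgre10 (4.75), and the largest falls in opn1sw1 (-6.88), opn1mw1 (-6.77), arr3a (-6.30), gnb3b (-5.92), opn1lw2 (-5.81) and gngt2b (-5.64).

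Of 18013 genes 12249 were called by limma, 3509 higher and 8740 lower (28.6% higher), or 6275 higher and 5048 lower after centring (55.4% higher), and 2604 changed at least 2-fold. Muscle genes fell in 34 of 36 cases (camera adjusted p = 2.2e-12), collagens in 22 of 23, or 23 adjusted over the list alone (adjusted p = 3.6e-07), and epidermal genes in 26 of 29, 16 after centring (adjusted p = 7.8e-05); in these 3 lists 0 rose. Heat shock genes rose in 20 of 25 cases (adjusted p = 1.7e-14), cell cycle genes in 22 of 39, with 8 lower, or 30 and 1 after centring (adjusted p = 3.6e-06), and liver, yolk and digestive genes in 13 of 23, with 3 lower, or 18 and 2 after centring (adjusted p = 3.5e-06). Eye and lens genes fell in 24 of 33 cases and rose in 7 (adjusted p = 0.00084). These 7 lists were called with an estimated correlation too, and the other 7 calls were lost with it. Oxidative phosphorylation fell in 37 of 41 cases (adjusted p = 4.8e-06; adjusted p = 0.16 with an estimated correlation). In the same terms, other lists were the spliceosome, with 24 of 50 higher and 9 lower, 38 and 3 after centring (7.8e-05 and 0.066) and unfolded protein response, with 12 of 34 higher and 8 lower, or 7 lower adjusted over the list alone, 21 and 4 after centring (0.0035 and 0.066). Others were inflammation, with 7 of 17 higher and 2 lower, 11 and 0 after centring (0.012 and 0.19), neurons and glia, with 24 of 33 lower, or 25 adjusted over the list alone, and 6 higher, 21 and 11 after centring (0.02 and 0.15), and TGF-beta components, with 9 of 25 higher and 7 lower, 15 and 4 after centring (0.039 and 0.15); 1 more list is not described. Counts adjusted over the list alone were the same in 19 of 24 lists. The other 10 lists, the globins in question among them, were not called (adjusted p from 0.15 to 0.99).

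**Figure D5:**
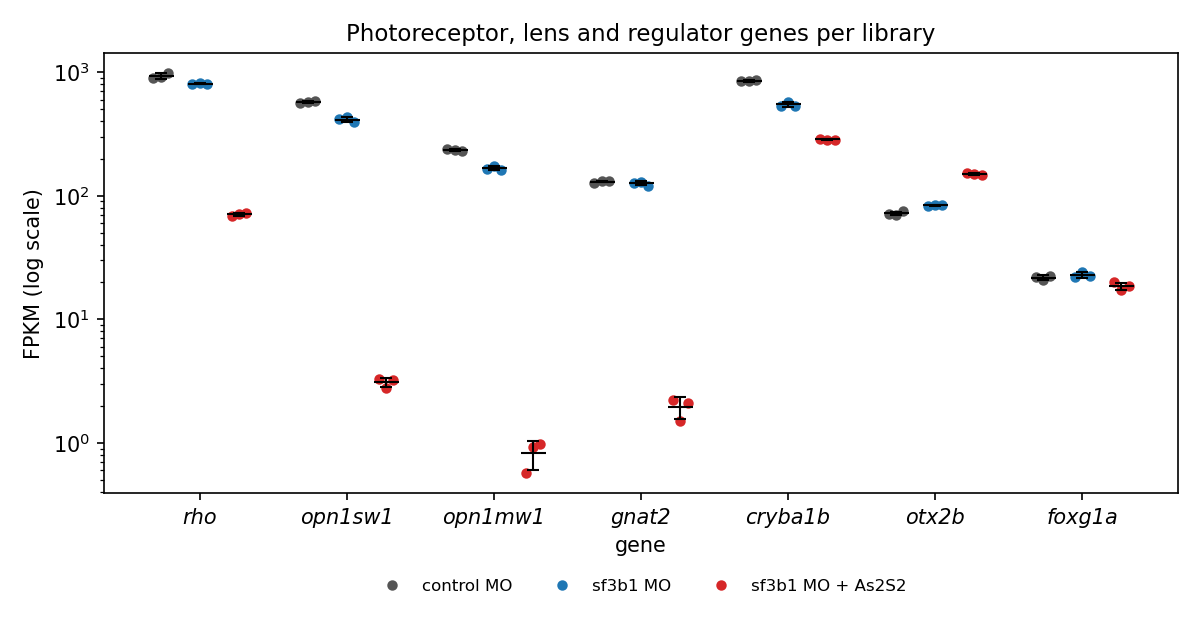
FPKM of photoreceptor genes (rho, opn1sw1, opn1mw1, gnat2), a lens gene (cryba1b) and regulator genes of eye and forebrain (otx2b, foxg1a) per library on a log axis; dots are libraries, bars the mean and SD of 3, and gnat2, cryba1b, otx2b and foxg1a were chosen after their values were seen. With As2S2, opn1sw1 stands at 3.09 FPKM and otx2b at 150 FPKM, above its level in both other groups.

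The last comparison asks which genes changed with the sf3b1 morpholino and changed back with As2S2, with both comparisons on FPKM. The vitamin B12 carrier gene tcnbb fell from 49.4 ± 0.613 to 13.8 ± 1.8 and stood at 61.9 ± 0.683 FPKM with As2S2 (SD, n = 3). The gene crtac1a went from 1.61 ± 0.406 to 13.7 ± 1.21 and 2.03 ± 0.396 FPKM, and fam204a from 2.03 ± 1.26 to 8.15 ± 2.75 and 1.80 ± 0.912. The receptor gene tnfrsf14 and the kinase gene pimr107 were listed at 0 in control MO, at 5.98 ± 0.662 and 3.12 ± 0.319 FPKM in the libraries labelled sf3b1 MO, and at 0.162 and 0.061 FPKM with As2S2; pimr102 stood at 0.136, 3.03 and 0.078 FPKM. The globins hbbe3 and hbbe1.1, which the rule also names, are in question. Of 18013 genes 3523 were called in both comparisons with opposite signs: 2406 higher and then lower, where independent lists would share 1865, and 1117 lower and then higher, where they would share 822. A further 751 were higher and 1726 lower in both, where independent lists would share 725 and 2114. After centring, 2006 were higher and then lower and 1535 the reverse, while 1535 were higher and 886 lower in both. The correlation of both sets of fold changes across genes was -0.152. In 100 simulations with no effect, sharing the sf3b1 MO libraries alone gave a mean correlation of -0.50 and 0 opposite calls. With no effect few genes can be called at all, so these 0 calls are no baseline for the 3523 observed. The observed covariance was -0.048, the simulated one -0.0154, and the difference -0.032. The 3 libraries shared by both comparisons cannot be split into parts of at least 2, so part of the opposite changes may come from them.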

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

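The tests of explanations in this part were all chosen after the results they measure were seen, while the splits of the libraries were planned before the data were examined.

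3 signals stood outside the values that the comparisons used. In 11 genes the deposited mean column differed from the mean of the control MO and sf3b1 MO FPKM. In 4 genes the FPKM of control MO followed the counts of the libraries labelled sf3b1 MO, and the reverse. For 386 genes or transcripts FPKM are listed in the As2S2 libraries alone, 134 of them at 1 FPKM or more in each As2S2 library, among them the histone gene hist2h3c at 36.3 ± 0.733 FPKM (SD, n = 3), chosen after its values were seen. Since the table lists no value for these genes in the other groups, no difference was computed.

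In the first pattern, the FPKM of 4 genes followed the other group's counts, and the deposited mean of 11 other genes differed. Of these 11, 10 are genes of blood. Counts and FPKM also parted in genes outside these 15, such as epyc, among the 57 whose ratios differed by more than 0.5. The tests of single genes below did not cover those. An exchange of whole libraries between groups is argued against by the correlation of 0.99 across genes between log2 ratios from counts and from FPKM. FPKM made from other reads or transcript models are argued against for the 11 genes with a differing mean, since all 11 had a set of FPKM values of the same gene, As2S2 values included, that gave the deposited mean within 1e-06. Values of single genes standing in the columns of another group may account for the 4 genes sf3b1, smad7, jun and hbbe3. In these, FPKM followed the other group's counts. Displaced values may also account for 9 of the 11 others. There, FPKM with As2S2 matched the rebuilt sf3b1 MO values library by library within 0.05. For hbbe2 too, the control MO FPKM, 34.07 ± 3.19, matched the rebuilt sf3b1 MO values, 34.06 ± 3.19, so displaced values may account for it. In alas2 and hbbe2 the only set that gave the deposited mean took columns of all 3 groups. How such values came to stand there cannot be read from the table, no biological explanation was tested, and the sign of the change between control MO and sf3b1 MO differs between counts and FPKM in these 4 genes and in others such as hbbe2 (0.72 and -0.86).

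The second pattern is that photoreceptor transcripts were lower with As2S2, with a median of -4.91 relative to the median gene over 11 genes. Missing eye and head tissue as the whole cause is argued against by 11 regulator genes of eye and forebrain, whose lower quartile was -0.05 and median 0.12. As this set joins eye and forebrain genes, it cannot decide whether eye tissue alone was lost. The 10 lens genes were all lower, with a median of -0.81, and neurons and glia had a median of -0.52. Scaling between groups is argued against by the upper quartile of the photoreceptor genes, at most -2.97 after median centring or quantile normalization. A younger or slower-maturing stage, or a separate library batch, which no label names, cannot be told apart from an effect of As2S2, since either would coincide with the group, and the cell cycle list was higher in them with a median of 1.06. A loss or delay of photoreceptors after As2S2 may therefore be 1 reading among these.

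The third pattern is that muscle, matrix and epidermal transcripts were lower in the libraries labelled sf3b1 MO. Scaling by a few abundant genes is argued against by the pooled upper quartile of the 3 lists, at most -0.78 under 4 other scalings or tools. A lower share of skeletal muscle alone had no independent test, since lower epidermal transcripts are part of the pattern itself. The values show only that other tissues moved apart, with the upper quartile of epidermis at -0.94 and the lower quartile of neurons and glia at -0.06. A younger stage would raise cell cycle genes, whose median was -0.41, but the morpholino itself could lower dividing cells, so stage and morpholino cannot be told apart. An effect of the sf3b1 morpholino on several tissues stays a hypothesis.

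For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05, and in each the real split alone, 1 of 10, gave a result as large. For sf3b1 MO against control MO the real split called 10592 genes and 10 lists, and the highest of the others 6 genes and 7 lists. For As2S2 against sf3b1 MO these were 11139 genes and 16 lists, against 3 genes and 13 lists, and for As2S2 against control MO 12249 genes and 14 lists, against 2 genes and 11 lists. Every other split mixes libraries of both groups and so puts their difference into the spread. Few gene calls there follow from this, so the splits cannot decide about chance. Mixed splits still called up to 7, 13 and 11 lists, so the number of lists called does not set the real split clearly apart. For the genes that changed back, 2 of 100 regroupings of the 9 libraries, the real one included, gave at least 3523 opposite calls. This share cannot decide whether chance is the source, since a mixed shared group puts the differences between groups into the spread. The 94 regroupings with a mixed shared group gave 0 to 2 opposite calls, and each one with an intact shared group gave at least 525. The result says only that the groups differ, not that genes returned to control MO. With the As2S2 libraries as the shared group 1 regrouping gave 6539, with control MO 2 gave 2573 to 2596, and with sf3b1 MO, the other libraries mixed, 2 gave 525 to 533, which points to a structure of the samples.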

How the results depend on the processing

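The alternatives based on FPKM as deposited or rebuilt for sf3b1 MO against control MO, rebuilt FPKM, median centring, quantile normalization, the filter at 5 FPKM, leaving out the genes in question, annotated genes alone, edgeR for the genes that changed back and their 2-fold limit were chosen after seeing the data; the others were planned. Of the values of named genes under the alternatives, 2289 kept direction and side of the threshold, 2 fell short of it and 6 reversed. Of the list results 839 stayed, 39 lost their call and 58 gained one.

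By FPKM as deposited, sf3b1 in sf3b1 MO against control MO was -0.66 and smad7 -0.41, reversed from counts, because the FPKM of these genes follow the other group's counts. With rebuilt FPKM, sf3b1 was -0.02 for As2S2 against sf3b1 MO and 0.65 against control MO without subtracting the median gene, and 0.19 and 0.90 relative to it. The globin list, hbbe1.1 and hbbe1.3 lost their call, an outcome fixed by FPKM with As2S2 that match the rebuilt sf3b1 MO values. Against control MO, sf3b1 was also higher after median centring, at 0.28, and quantile normalization, at 0.10, since both remove the shift of the median gene.

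At least 2-fold changes numbered 2437 for sf3b1 MO against control MO, 1713 for As2S2 against sf3b1 MO and 2604 for As2S2 against control MO. With this limit in both comparisons, 129 genes changed back, while 32 were higher and 72 lower in both. With at least 5 FPKM in 3 libraries, 7820 genes were called for As2S2 against control MO, of fewer genes tested. Without 1 library at a time, calls ranged from 9256 to 9929, 10282 to 10498 and 11051 to 11582 in the 3 comparisons, genes changed back from 2927 to 3422, and the correlation of fold changes from -0.17 to -0.15.

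With an estimated correlation 3 lists were called for sf3b1 MO against control MO and 7 for As2S2 against control MO. The directional test of fry called 16 lists in the former, and its mixed test 24 in both; fry does not compare a list with other genes. Its directional test lost the spliceosome for As2S2 against sf3b1 MO (adjusted p = 0.059) and TGF-beta components for As2S2 against control MO (0.075). For sf3b1 MO against control MO, neurons and glia lost their call without control MO replicate 1 (adjusted p = 0.05), 2 (0.068) or 3 (0.054) or sf3b1 MO replicate 3 (0.057), and notochord and pigment cells without control MO replicate 1 (0.06) or 2 (0.063) or sf3b1 MO replicate 1 (0.064). The erythroid list gained a call without sf3b1 MO replicate 1 (0.038). For As2S2 against sf3b1 MO, inflammation gained one without sf3b1 MO replicate 3 (0.049). For As2S2 against control MO, TGF-beta components lost theirs without control MO replicate 3 (0.056) or As2S2 replicate 2 (0.085) or 3 (0.086), and inflammation without As2S2 replicate 2 (0.052) or 3 (0.059). With the replicate number as block, though nothing shows pairing, 7 lists were called for sf3b1 MO against control MO: TGF-beta targets, neurons and notochord were lost, each at 0.06. By FPKM in place of counts, the same comparison lost neurons (0.13 as deposited, 0.085 rebuilt), notochord (0.13 and 0.11) and, as deposited, the spliceosome (0.13). It gained the erythroid list (0.04 and 0.046) and, as deposited, the globins in question. For As2S2 against control MO, ribosome biogenesis gained a call after median centring (0.0099) and quantile normalization (0.039). Except where a reason is given, the cause was not tested.

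Alternatives on counts were not run for the As2S2 libraries, since the table holds FPKM for them, and their unknown depth limits what low FPKM can show. The filter on low counts removed no gene, so that alternative says nothing about stability.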

Other observations

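The tests and genes in this part were all chosen after their values were seen.

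Regulator genes of eye and forebrain parted from photoreceptor genes with As2S2. The homeobox gene otx2b stood at 72.1, 83.6 and 149.8 FPKM in control MO, the libraries labelled sf3b1 MO and those with As2S2. In the same order, the cone transducin gene gnat2 stood at 130.3, 126 and 1.95 FPKM, the lens gene cryba1b at 849, 548 and 286 FPKM, and the forebrain gene foxg1a at 21.7, 22.8 and 18.6 FPKM. Over 10 lens genes the median change with As2S2 against sf3b1 MO was -0.81 relative to the median gene.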
